A study of Mus musculus with 15 samples.

How the data were processed

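The deposited table holds unnormalised read counts per gene, for 39179 mouse gene identifiers in 15 libraries, and the values were checked to be whole numbers before use. Total RNA was extracted with Trizol and made into libraries with a stranded mRNA kit. The submitters' processing notes name TopHat2 2.0.4, SAMtools, Cufflinks, HTSeq 0.6.1, DESeq2 and the genome build GRCm38. The annotation release, the strand setting of the counting, the handling of reads that match several places, and the time between injury and tissue collection are not given in the sources used here. Gene symbols, coordinates and 3′ UTRs were taken from GENCODE M21 on GRCm38, which gave a symbol to 37607 of the identifiers, and the identifiers without one hold 0.523% of the counts.

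Of 27310 genes with a count, 16976 were tested after the filterByExpr filter of edgeR by group, with its default minimum count of 10. The genes left out hold 0.131% of the counts. One model with 4 group means was fitted to the 15 libraries with edgeR 4.0.16 (TMM factors, estimateDisp, robust quasi-likelihood F test), which leaves 11 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 16976 genes. Levels are CPM scaled by TMM, log2 CPM used a prior count of 2, and the SE of a log2 fold change is its size divided by the square root of F. For a gene with no count in any library of a group, the bound on the fold uses 3 counts over that group's libraries, and such bounds cover counting error only. Tests were two-sided.

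The tests of genes and lists, the seed-site shift of 8mers in knockout against control and for injury in control, the overlap of knockout and injury changes, the gene lists, the rule for naming genes and the alternatives were chosen before the data were examined, except where the closing section says otherwise. Added later were the shares of called genes with a site, the shifts for single microRNAs and for injury in knockout, and the comparison of calls between sets of libraries that share none. Genes named in the text are Cacna2d1, Cacna2d2, Scn3a, Bdnf, Atf3, Wnt1 and the microRNA genes of the cluster. In each comparison they are also the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 1 CPM and no overlap between the groups, without predicted and clone names and sex-linked genes. Where fewer than 5 genes pass, the 5 with the smallest p are named. Of each list described, up to 4 members with the smallest p are named. Not every gene that these rules give is named.

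The 33 gene lists were tested with camera of limma 3.58.1 on voom values of the same model, with a preset correlation of 0.01 and adjustment over the lists of a comparison. An estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. Seed sites were 8mers of miR-183-5p (GTGCCATA), miR-96-5p (GTGCCAAA) and miR-182-5p (TTGCCAAA) in the longest annotated 3′ UTR. Genes with at least 1 of them were compared with genes that have an annotated 3′ UTR and neither an 8mer nor a 7mer-m8 site, by an exact permutation test over the libraries on the mean difference of log2 CPM. The same measures were taken for 1000 triples of other 8mers ending in A, drawn to match the cluster's sites in gene number. Shares of genes with a site were compared by Fisher's exact test, which counts genes as independent. Its p values and intervals therefore hold no spread between animals.

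Overlap between comparisons that share the control naive libraries was set against simulations with unchanged groups and against every split of those 5 libraries into 2 and 3. Alternatives used DESeq2 1.42.0, limma-voom and sva 3.50.0, in R 4.3.3 and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Simulated counts with known changes measured recovery. At a true 2-fold change the fit recovered 71.6% in naive animals, 80.6% for injury in control, 62.7% for injury in knockout, 64.2% for knockout against control after injury, and 46.3% for the difference between injury effects. Every simulated library had the same spread for a gene, whereas the median SD of control SNI was 2.01 times that of knockout SNI. These shares therefore do not rank the comparisons by power.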

Results

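Messenger RNA of the lumbar 4 to 6 dorsal root ganglia (DRG), which hold the sensory neurons of the hind limb, was sequenced from 15 mice of 3 to 6 months. Control mice (Wnt1-Cre or wild type) were compared with mice in which Wnt1-Cre removes the floxed miR-183 cluster, the genes of miR-183, miR-96 and miR-182, from cells of the neural crest. The naive groups held 5 control and 4 knockout animals. The groups with spared nerve injury (SNI), in which the common peroneal and tibial nerves are tied and severed and the sural nerve is left, held 3 control and 3 knockout animals. Each animal gave 1 library. Among the controls, naive replicate 7 and SNI replicates 18 and 23 were wild type and the others carried Wnt1-Cre.

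The control naive libraries (replicates 1, 2, 3, 6 and 7) held 9.96, 8.78, 10.5, 10.8 and 10.5 M counts. The knockout naive libraries (4, 5, 8 and 9) held 9.70, 9.98, 10.3 and 7.59 M, the control SNI libraries (15, 18 and 23) 9.62, 9.40 and 5.25 M, and the knockout SNI libraries (13, 19 and 21) 8.08, 10.8 and 10.2 M. A count of 0 therefore allows a level of up to 0.277 to 0.571 CPM in a single library, by counting error alone. The microRNA genes themselves (chromosome 6, 30165918 to 30169737) are too short for this assay. Mir183 had 0, Mir96 1 and Mir182 2 counts over all libraries, so the deletion could not be read from them. Wnt1 had 8 counts. Pairs of libraries within a group had Spearman correlations across genes of 0.953 to 0.993, and 0.982 or more without control SNI replicate 23. The common biological coefficient of variation was 15.3%.

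The first principal component held 26.5% of the variance and parted the injured from the naive libraries, except control SNI replicate 23, which lay at -30.4, below the naive ones (-21.1 to -8.62). That library also stood apart on the second, which held 20.2%. In that library 7.43% of the counts were mitochondrial, against 2.26 to 3.60% in the other 14, and its level of cytosolic ribosomal protein transcripts was the highest of the 15.

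**Figure D1:**
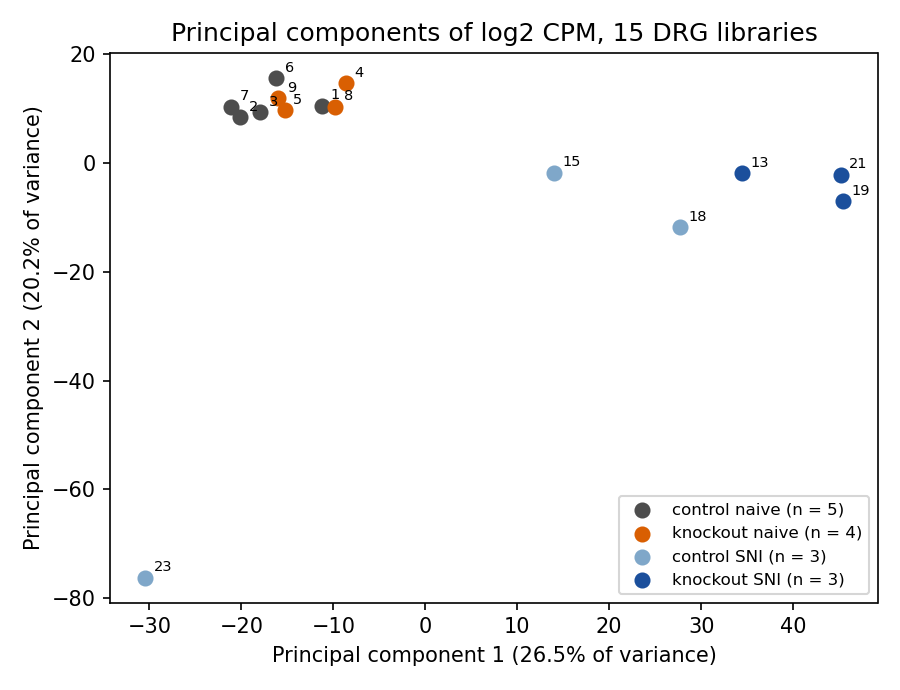
Each point is 1 of the 15 libraries on the first (26.5% of variance) and second (20.2%) principal component of log2 CPM, coloured by group and labelled with its replicate number. Control SNI replicate 23 lies at -76.2 on the second component.

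The first comparison, knockout against control in naive animals, asks which DRG transcripts depend on the cluster without injury. Slc25a1, the mitochondrial citrate carrier that feeds lipid synthesis (chromosome 16, 17925223 to 17928219), rose to 254 ± 18.2 CPM (SD, n = 4) from 91.9 ± 5.00 (n = 5), a log2 fold change of 1.46 (SE 0.0805, adjusted p = 3.38e-08). Cacna2d2, an auxiliary subunit of voltage-gated calcium channels that gabapentinoid drugs bind (chromosome 9, 107399612 to 107529343), rose from 47.4 ± 3.71 to 97.3 ± 6.87 CPM (log2 1.04, SE 0.127, adjusted p = 2.2e-04). Cacnb1, another calcium channel subunit, rose by 0.60 on the log2 scale, and was not called without knockout naive replicate 9 (adjusted p = 0.062). Cacna2d1, the better known gabapentinoid target, was not called (log2 0.12, adjusted p = 0.67), nor were Scn3a (0.27, adjusted p = 0.387), Bdnf (-0.18) and Atf3 (-0.48). The glutamate transporter Slc1a1 rose from 6.80 ± 0.739 to 19.5 ± 2.48 CPM, the signalling regulator Rgs2 from 16.6 ± 2.09 to 36.1 ± 3.12, and the growth cone gene Gap43 from 195 ± 19.5 to 357 ± 14.8.

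Itch and touch receptor genes moved in both directions. The receptors Mrgpra3, Mrgprb4 and Mrgprx1, of 1 family of similar paralogs that mark itch and stroking neurons, rose by 1.70, 1.91 and 0.91 on the log2 scale, and Mrgpra3 went from 17.4 ± 1.80 to 56.1 ± 14.3 CPM. Il31ra, the interleukin-31 receptor of another class of itch neurons, went the other way, from 31.6 ± 5.42 to 6.96 ± 2.34 CPM (log2 -2.19, SE 0.222, adjusted p = 5.5e-05). All 11 markers of that class, which makes somatostatin and natriuretic peptide, were lower, with a median log2 of -0.46. Il31ra and Ptprk passed on their own, and the call of Ptprk was lost on leaving out any 1 naive library (adjusted p up to 0.131, without knockout naive replicate 8). The adjusted p of the list was 1.42e-06, and 0.141 with an estimated correlation. P2rx3, the ATP receptor of non-peptidergic nociceptors, fell from 233 ± 43.3 to 124 ± 15.1 CPM, and the acid-sensing channel gene Asic3 from 111 ± 4.54 to 64.6 ± 9.46. Of 17 markers of non-peptidergic nociceptors, 3 rose and 4 fell (adjusted p = 0.00916 for lower, 0.975 with an estimated correlation).

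In all, 321 of 16976 genes passed, 151 higher and 170 lower, and 34 of the former and 46 of the latter changed at least 2-fold. The groups did not overlap for 316 of these called genes. Over all tested genes the share was 9.63%, against 1.59% by chance. The largest rises beside Slc25a1, Slc1a1, Mrgpra3 and Mrgprb4 were those of Lgals7, Tekt2, Zdbf2, Ung, Galr1 and Rspo4 (log2 1.36 to 2.13). Tekt2 was not called by limma-voom, and Ung was not called without knockout naive replicate 4 or 9 (adjusted p up to 0.0622). The largest falls were those of Sycp1, Calhm4, Clec18a, Slc51a, Il31ra, Htr1a, Ccl25, Dnah6, Ceacam10 and C1ql4. Sycp1 had no count in the 4 knockout libraries and 2.69 ± 0.481 CPM (n = 5) in control, at least 34.2-fold lower by 3 counts over the group. The others fell by 1.76 to 3.16 on the log2 scale. Slc51a was not called without knockout naive replicate 4 or 9, Ceacam10 without 4 of the 9 naive libraries and Ccl25 without 8 of them (adjusted p up to 0.0655, 0.0828 and 0.0899). Leaving out 1 library gave 151 (knockout naive replicate 9) to 229 genes (control naive replicate 3).

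**Figure D2:**
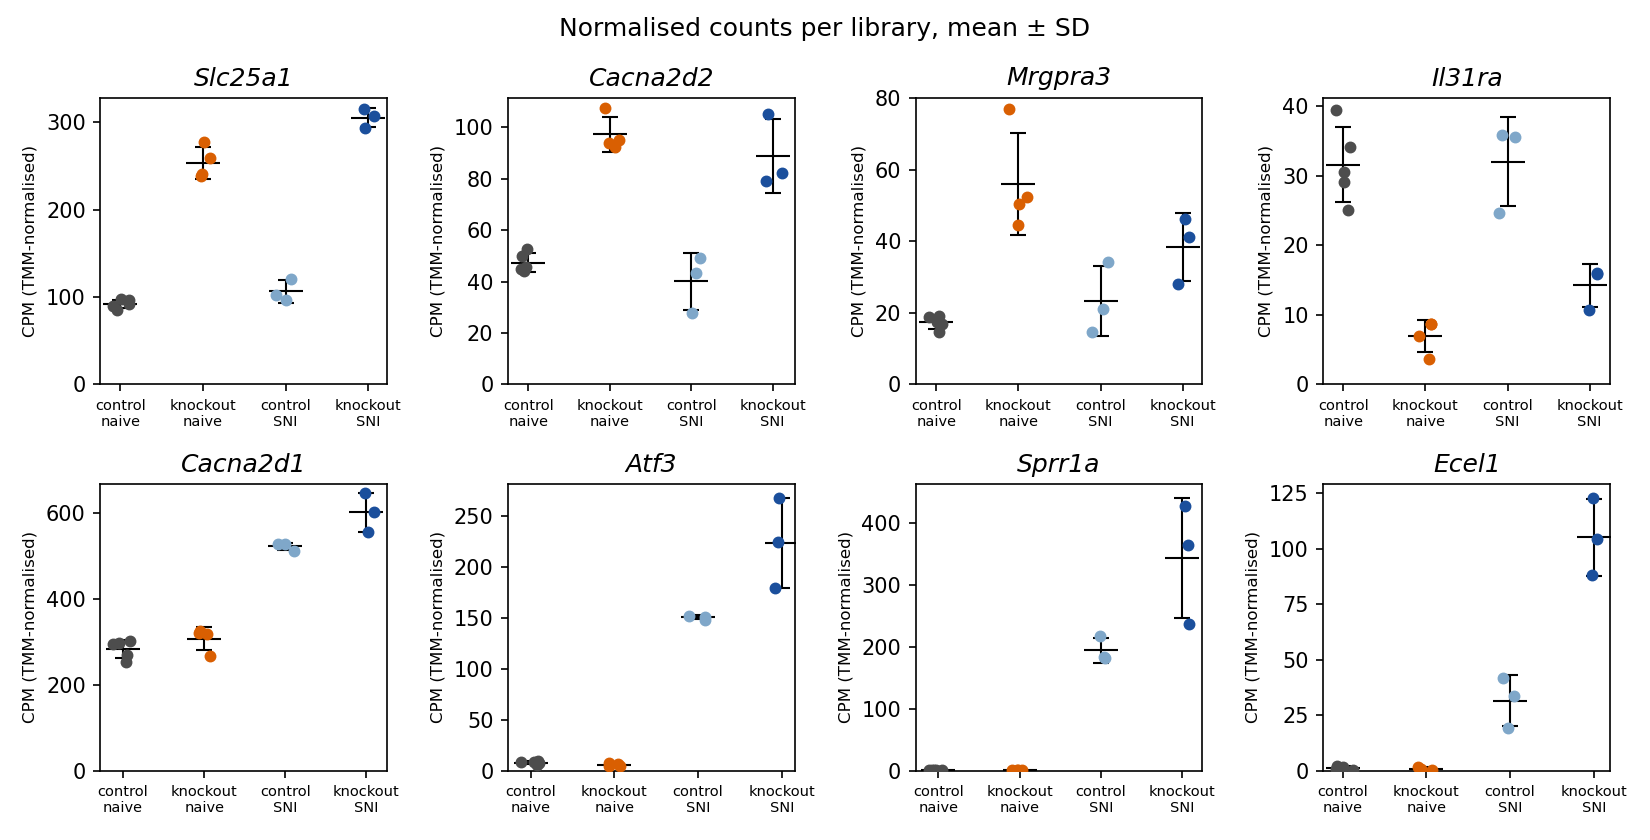
Normalised CPM of 8 genes in each of the 15 libraries (points), with group means and SD (bars), for 5 control naive, 4 knockout naive, 3 control SNI and 3 knockout SNI animals. Slc25a1 and Cacna2d2 were higher in every knockout than in every control library of the same condition, whereas Atf3, Sprr1a and Ecel1 were high after injury in both genotypes.

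Seed sites of the deleted microRNAs were common among the genes that rose in naive knockout animals. Of 143 such genes with an annotated 3′ UTR, 68 (47.6%) carried an 8mer of the cluster, among them Slc25a1, Cacna2d2, Slc1a1, Rgs2, Galr1 and Zdbf2, against 8.94% of the genes that were not called. The odds ratio was 9.23 (95% interval 6.51 to 13.1, Fisher's exact p = 1.18e-32), and it was 0.997 for the genes that fell, of which 14 of 157 carried a site. That p and interval count genes as independent and hold no spread between animals. Mrgpra3, Mrgprb4 and Mrgprx1 have short 3′ UTRs without a site. Over all expressed genes the 1347 genes with a site lay 0.06 log2 units above the 10572 without (SE 0.0153, exact permutation p = 0.00794, the smallest possible). The adjusted p over the 20 shifts measured was 0.0529, which misses 0.05. The shift was 0.16 for miR-96-5p sites, 0.04 for miR-183-5p and 0.03 for miR-182-5p (exact p = 0.198). With 7mer-m8 sites added it was 0.02 (exact p = 0.167). A set of 34 published targets of the cluster, to which Cacna2d2 and Rgs2 belong, lay higher (adjusted p = 3.09e-04, 0.0579 with an estimated correlation), with 2 genes called over all genes and 3 adjusted over the list alone. The set was written from background knowledge, without a source for each gene. Whether reports on these same animals supplied any member, such as Cacna2d2, is not recorded, so the set may not be independent of these data.

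**Figure D3:**
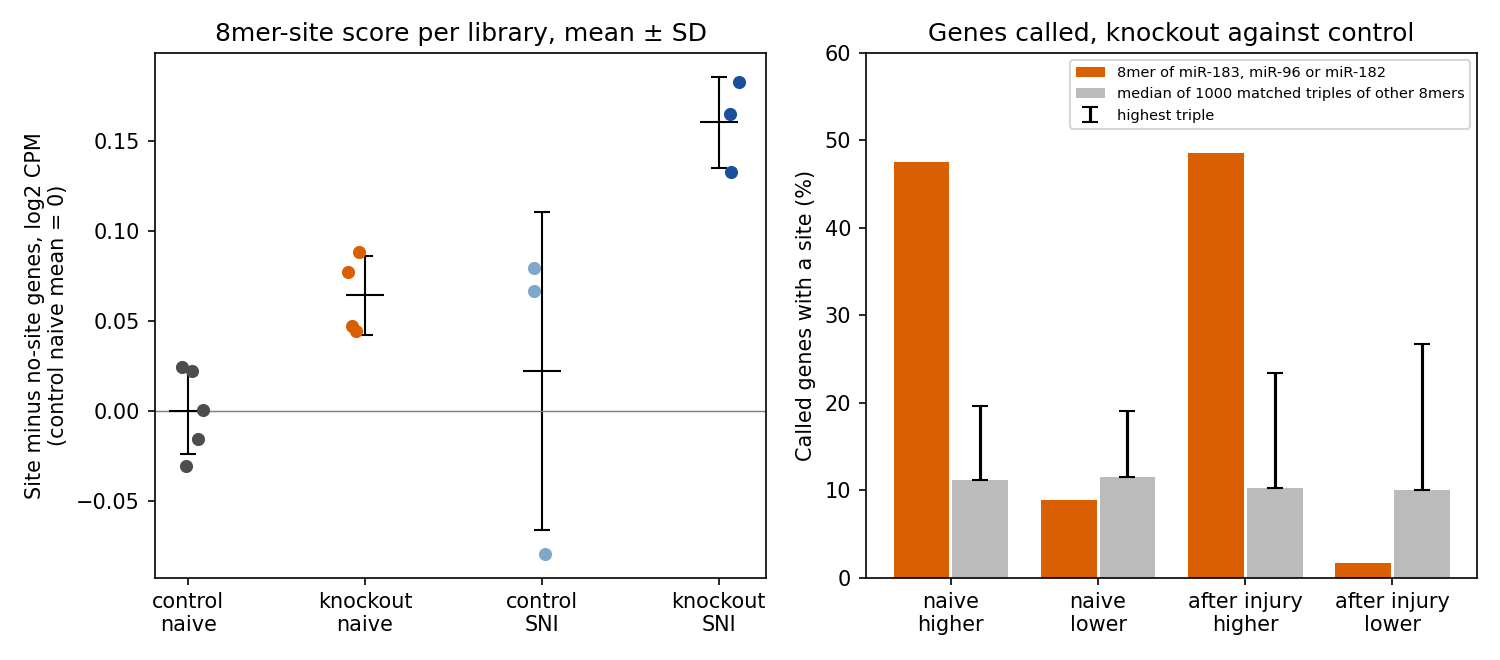
Left, the mean log2 CPM of genes with an 8mer site minus that of genes without, per library (points, control naive mean set to 0), with group means and SD; the 4 knockout naive libraries lie at 0.0442 to 0.0883. Right, the percentage of genes called higher in knockout that carry a site, 47.6 in naive and 48.6 in injured animals, beside the median of 1000 matched triples of other 8mers (11.2 and 10.3), with a line up to the highest triple.

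Cholesterol synthesis genes lay slightly higher in naive knockout animals, 21 of 24 of them, with a median log2 of 0.14 and no gene called (adjusted p = 9.22e-05, 0.581 with an estimated correlation). The other lists with a call all had an adjusted p of 0.787 or more with an estimated correlation. The ribosomal protein genes (5.18e-04), skeletal muscle markers (0.00581) and macrophage markers (0.0193) were higher, and the mechanosensitive and TRP channels (0.0103), opioid and GABA receptors (0.0143) and C low-threshold mechanoreceptor markers (0.03) lower. Of these, each but the ribosomal genes lost its call on leaving out 1 library. The muscle markers went to 0.267 without knockout naive replicate 8, the macrophage markers to 0.259 and the C low-threshold markers to 0.134 without knockout naive replicate 4. The opioid and GABA receptors went to 0.0676 without knockout naive replicate 9, the non-peptidergic markers to 0.0576 without knockout naive replicate 8, and the mechanosensitive channels to 0.0539 without control naive replicate 6.

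Injury against naive in control animals compares ganglia of severed nerves with uninjured ones, in animals from separate ranges of animal numbers. Sprr1a, a gene of regenerating axons, rose from 0.808 ± 0.417 (n = 5) to 194 ± 20.2 CPM (SD, n = 3; log2 7.93, SE 0.261, adjusted p = 4.06e-11). The injury transcription factor Atf3 rose from 7.86 ± 1.5 to 151 ± 1.95 CPM (log2 4.26, SE 0.166, adjusted p = 7.27e-11), and the neuropeptide genes Npy, Nts and Gal rose by 6.84, 4.35 and 3.35 on the log2 scale. Cacna2d1 rose from 284 ± 21 to 523 ± 8.58 CPM (log2 0.88, SE 0.0865, adjusted p = 9.67e-06), while Cacna2d2 (-0.22), Scn3a (-0.02) and Bdnf (0.79, adjusted p = 0.122) were not called. Of 37 nerve injury genes tested 27 rose, 32 adjusted over the list alone (list adjusted p = 3.19e-58, and 0.00322 with an estimated correlation). Macrophage genes rose too, 12 of 27 and none fell, among them Cx3cr1, C1qb, C1qc and Lgals3 (log2 1.15 to 1.55). The adjusted p of the macrophage list was 7.53e-17, and 0.193 with an estimated correlation. Its fry adjusted p was 0.0099, but fry does not set a list against other genes, so it does not offset the 0.193. Fry values of the other lists are not given here.

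In all, 421 genes passed, 360 higher and 61 lower, of which 175 and 13 changed at least 2-fold. The groups did not overlap for 395 of these, and for 8.21% of all tested genes, where chance gives 3.57%. Sprr1a, Anxa10, Npy, Lipn, Cckbr, Slc6a4, Ecel1, Fgf3, Gpr151 and Nts had the largest rises (log2 4.35 to 7.93). Calb2, Comp, Bnc1, Dnah6, Tnfaip8l3, Zbtb32, Atp8b5, Cldn9 and Slc6a7 were among the largest falls, by 1.05 to 1.88. Calb2, the calcium buffer calretinin, fell from 10.4 ± 0.922 to 2.96 ± 1.08 CPM. Dnah6 was not called without control SNI replicate 18 (adjusted p = 0.0999). Zbtb32, Cldn9, Bnc1, Slc6a7 and Comp each lost their call without any of 3 to 7 of the 8 libraries, with adjusted p up to 0.0888 for Slc6a7 and 0.161 for Cldn9. The count was 283 without control SNI replicate 18, 796 without replicate 23 and 1506 without replicate 15.

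Myelinating Schwann cell markers were lower (adjusted p = 2.13e-05, with Ugt8a called and lost without any of 7 of the 8 libraries, adjusted p up to 0.148) and complement and cytokine genes higher (5.71e-05, 3 of 24 called). The estimated-correlation values were 0.735 and 0.533, and 0.735 for the lists that follow. Ribosomal protein genes were higher (2.29e-05), but not without control SNI replicate 23 (0.859). Oxidative phosphorylation genes, not called with all libraries, were lower without it (2.25e-08). The major histocompatibility genes (0.0139), adipocyte markers (0.0276) and immediate early genes (0.0347, Atf3 and Jun called) were higher. The mechanosensitive and TRP channels (0.0347), sodium channels (0.0453) and A-fibre markers (0.0453) were lower. Each of these 6 lost its call on leaving out 1 library. The highest adjusted p values among such omissions were 0.0992 for the histocompatibility genes (without control SNI replicate 15), 0.316 for the adipocyte and 0.367 for the A-fibre markers (replicate 18), 0.138 for the immediate early genes (control naive replicate 7), and 0.887 and 0.443 for the mechanosensitive and sodium channels (control SNI replicate 23).

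The same contrast in knockout animals compares injured with naive ganglia without the cluster, again from separate ranges of animal numbers. Sprr1a rose from 0.848 ± 0.379 (n = 4) to 343 ± 97.0 CPM (SD, n = 3; log2 8.69, SE 0.29, adjusted p = 2.53e-11) and Atf3 from 5.61 ± 1.41 to 224 ± 44.2 (log2 5.31, SE 0.19). Ecel1, a protease gene of injured neurons, rose from 0.705 ± 0.723 to 105 ± 17.4 CPM, and Cacna2d1 from 308 ± 27.0 to 602 ± 46.0 (log2 0.97, SE 0.0913, adjusted p = 3.87e-06). Cacna2d2 (-0.13), Scn3a (0.21) and Bdnf (0.23) were not called. Of the 37 nerve injury genes 28 rose (list adjusted p = 1.33e-35, and 0.0236 with an estimated correlation), among them Csf1, the growth factor that draws microglia and macrophages, by 2.06 on the log2 scale. Of 23 immediate early genes 6 rose, with Jun at 1.66 (adjusted p = 1.59e-05, 0.611 with an estimated correlation). Macrophage markers (8 of 27 called, Csf1r at 0.94) and complement and cytokine genes (4 of 24) were higher, with adjusted p of 2.11e-06 and 3.48e-04, and 0.611 for both with an estimated correlation. The published targets of the cluster were higher, 7 of 34 called (adjusted p = 0.00768, 0.204 with an estimated correlation), with Cacna2d1 and Gpc1 (log2 0.92) among them.

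In all, 1717 genes passed, 1218 higher and 499 lower, of which 319 and 46 changed at least 2-fold. The groups did not overlap for 1669 of these, and for 34.2% of all tested genes, where chance gives 5.71%. The largest rises were those of Sprr1a, Npy, Ecel1, Cckbr, Slc6a4, Atf3 and Kcnk16 (log2 5.17 to 8.69) and of Anxa10, Lipn and Ucn, which had no count in the 4 naive knockout libraries and were at least 125, 124 and 29.8-fold higher by 3 counts over that group. The largest falls were those of Calb2, Scgn, Tceal7, Ccl28, Bex4, BB218582, Elf5, Mybl2, Chodl and Phf2os1, by 1.31 to 2.21 on the log2 scale. Of these, only the call of Calb2 was kept on leaving out any 1 library. For the others the adjusted p without knockout SNI replicate 19 or 21 reached 0.0667 (Bex4) to 0.209 (Phf2os1). Phf2os1 is an antisense gene and depends on the strand setting. The count was 587 without knockout SNI replicate 19, 802 without replicate 21 and 870 without knockout naive replicate 8.

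Oxidative phosphorylation (2.26e-05) and ribosomal protein genes (0.00411) were lower and skeletal muscle markers (4.05e-05), extracellular matrix genes (3.58e-04) and adipocyte markers (0.00626) higher, with an adjusted p of 0.992 for each with an estimated correlation. Of the muscle markers Ryr1 was called, and not without knockout SNI replicate 21 (adjusted p = 0.0866). The adipocyte markers went to 0.224 without knockout SNI replicate 19. The injury calls of the genotypes share no library. Of the 421 genes called in control animals, 415 (98.6%) changed with the same sign and 306 were called in both, 274 higher and 32 lower, against 25.8 and 1.79 for independent lists. The median log2 size of the 421 was 0.92 in control and 0.90 in knockout animals. The 1717 genes picked by their call in knockout had 0.61 there and 0.24 in control animals, with the same sign for 89.4%.

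Knockout against control after injury sets injured ganglia without the cluster beside injured control ganglia. The injured knockout animals carry numbers 948 to 956 and the injured controls 974 to 976, so genotype and that order cannot be told apart. Control SNI replicates 18 and 23 also lack the Cre allele, which every knockout carries. Slc25a1 was again higher, at 306 ± 10.9 against 107 ± 12.8 CPM (SD, n = 3 and 3; log2 1.52, SE 0.1, adjusted p = 5.81e-07), as was Cacna2d2, at 88.9 ± 14.4 against 40.1 ± 11 (log2 1.13, SE 0.159, adjusted p = 0.00185). B4galnt1, an enzyme of ganglioside synthesis, stood at 90.1 ± 9.11 against 27.1 ± 7.81 CPM and the exchange factor Rasgrf1 at 59.6 ± 7.75 against 22.3 ± 6.26. Csf1 rose by 0.97, the potassium channel gene Kcnk18 by 1.19, and Cacnb1 by 0.87 on the log2 scale. Calb2 stood at 0.651 ± 0.256 against 2.96 ± 1.08 CPM, and Il31ra and Nts fell by 1.17 and 1.5. The calls of Il31ra and Nts were lost without control SNI replicate 23 or any knockout SNI library (adjusted p up to 0.157 and 0.153). Atf3 (0.57, adjusted p = 0.105), Cacna2d1 (0.20), Scn3a (0.51, adjusted p = 0.108) and Bdnf (-0.73) were not called.

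In all, 177 genes passed, 113 higher and 64 lower, of which 26 and 32 differed at least 2-fold. The groups did not overlap for any of the 177, and for 16.2% of all tested genes, where chance gives 10%. Tekt2, Zdbf2, Ecel1, B4galnt1, Slc25a1, Rasgrf1, Islr2, Nrsn2, Fam78a and Slc1a1 had the largest rises (log2 1.28 to 2.23). Calhm4, Slc51a, Ceacam10, Calb2, Ly86, Btc, Chst9, Chodl, Chrnb3 and Hyi had the largest falls, by 1.52 to 3.58. Among the rises Ecel1, Islr2, Fam78a and Tekt2, and among the falls Slc51a, Ceacam10, Ly86, Btc, Chst9 and Chodl, each lost their call without any of 2 to 5 of the 6 libraries. Their highest adjusted p, without knockout SNI replicate 19 or 21, went from 0.0623 (Slc51a) to 0.197 (Fam78a). A fit of the 6 injured libraries alone called 0 genes in edgeR, and with all 4 groups in the model DESeq2 called 925. The count was 57 without knockout SNI replicate 19, 63 without replicate 21, 435 without control SNI replicate 18 and 3558 without replicate 15.

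Of the 321 genes called in naive animals, 292 (91.0%) had the same sign after injury, in libraries that are all different, and 81 were called in both conditions with no opposite sign. Among the genes higher in injured knockout than injured control animals 52 of 107 (48.6%) carried an 8mer of the cluster (odds ratio 9.48, 95% interval 6.33 to 14.2, Fisher's exact p = 9.32e-26), against 1 of 60 that were lower. Here too Fisher's test holds no spread between animals. The shift over all genes was 0.14 (exact permutation p = 0.1, the smallest that 3 against 3 can give). Control SNI replicate 23 widens it: its score of site minus no-site genes was -0.0796, against 0.0666 and 0.0791 in the other control SNI libraries. The knockout SNI libraries scored 0.133 to 0.183. The published targets were higher, with 1 gene, Cacna2d2, called over all genes and 11 adjusted over the list alone (list adjusted p = 2.1e-05, and 0.0246 with an estimated correlation). Here too the set may not be independent of these data.

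**Figure D4:**
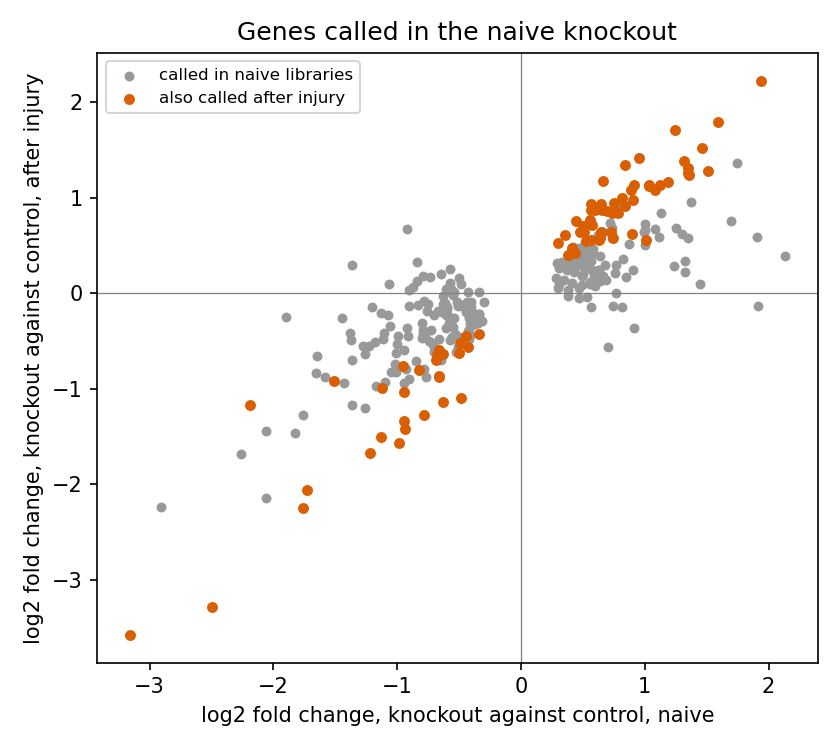
Log2 fold change of knockout against control in naive (horizontal) and injured (vertical) animals for the genes called in naive animals, without Sycp1. Of the 321 genes, 292 had the same sign, and those called in both conditions (81) are in orange.

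Pruriceptor markers were lower after injury too (adjusted p = 1.35e-04, 0.506 with an estimated correlation, Il31ra and Nts called). The remaining called lists all had 0.659 with an estimated correlation. Muscle markers (6.25e-07), immediate early genes (4.76e-04), nerve injury genes (0.00127), cholesterol synthesis genes (0.00834) and calcium channel subunits (0.00902) were higher, and oxidative phosphorylation (6.25e-07) and ribosomal protein genes (2.03e-05) lower. Without control SNI replicate 23, the oxidative phosphorylation genes went to 0.0627, the ribosomal genes to 0.283 and the calcium channels to 0.121. The cholesterol list went to 0.125 without control SNI replicate 18 and the nerve injury list to 0.0997 without knockout SNI replicate 19. The muscle scores of knockout SNI replicates 13, 19 and 21 and of control SNI replicate 18 lay between 1.64 and 4.30, against -1.22 and -0.80 in the other control SNI libraries.

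Whether the injury effect itself differs between the genotypes was tested as an interaction. No gene passed in edgeR, with 2281 at an unadjusted p under 0.05. DESeq2 called 12 and limma-voom 0. The smallest p values belonged to 1700048O20Rik (log2 -1.94), Flnc (1.61), Trp53i11 (1.17), 4833420G17Rik (-1.27) and Adgrd1 (1.66), with adjusted p of 0.0872 for the former pair and 0.245 for the rest. For Atf3 the difference was 1.05 (adjusted p = 0.365) and for Cacna2d1 0.09. Leaving out control SNI replicate 15 gave 1235 genes, and any other library at most 1.

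The title of the series links basal and neuropathic gene pathways, so the naive knockout changes were compared with the injury changes of control animals, which share the 5 control naive libraries. Of the 321 and 421 genes, 11 were higher in both and 11 lower in both, among them Gap43, and Calb2 and Dnah6. Independent lists would give 3.20 and 0.611. With opposite signs, 6 genes were lower in knockout and higher after injury, against 3.6 for independent lists. The reverse held for 0 genes, against 0.543. The shared controls affect each of these counts, so the values for independent lists are not chance values. With the shared controls split so that each comparison had its own, the medians over 20 splits were 3 higher and 2 lower in both, out of fewer calls (medians of 116 for knockout and 207 for injury). The covariance of the log2 fold changes across genes, which are not independent replicates, was 0.0231, against 0.0207 (0.0182 to 0.0244 in 20 simulations) with unchanged groups. With the split controls its mean was 0.00819 (0.00279 to 0.0123 over the 20 splits). Pearson's r across genes was 0.228, against 0.390 (0.359 to 0.435) in the simulations and a mean of 0.0698 with the split controls. The simulations gave every library the spread of the joint fit, although the median SD was 0.307 in control SNI and 0.15 in control naive libraries. They are therefore no firm expectation for the shared controls. Injury in control animals moved the genes with an 8mer by 0.02 (exact permutation p = 0.607), and by 0.07 without control SNI replicate 23 (exact p = 0.0476). The latter p is the smallest that the libraries left can give. It is not adjusted and belongs to a single omission among several.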

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

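The splits of the libraries for the first 4 comparisons were chosen only after the result was seen. So were the shares of called genes with a seed site, the scatter within groups and the test for a larger injury response. The use of fits without wild-type controls to explain the naive differences was also chosen then, although the fits were fixed in advance. The splits for the injury effect compared between genotypes, the matched triples of other 8mers among called genes and the test of the flanking genome were set out before their own result was seen.

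Single libraries stood apart from the rest of their group for 7 genes and 5 list scores, measured as the gap to the nearest library over the range of the group. Of 216 groups of 4 or 5 libraries 12 passed Dixon's critical value, where chance gives about 1 in 20. Knockout naive replicate 9 was low for Cacna2d1 (268 CPM against 318 to 325, gap 0.889), Comp (gap 0.88) and the score of the extracellular matrix genes (0.834), and high for red blood cell genes (0.845). Knockout naive replicate 8 was the only naive knockout library with Npy (0.760 CPM against 0, gap 1), and Zdbf2 was low in knockout naive replicate 5 (0.86). Among control naive libraries, replicate 6 was low for Lipn (0.803), at 0 counts, replicate 3 for Trp53i11 (0.715), and replicate 1 was the only one with a count of Ucn (gap 1). Replicate 1 was also high for the published targets of the cluster (0.788), replicate 3 for adipocyte markers (0.889), and replicate 6, the only one of them with a female level of Xist, stood apart on the sex-linked genes (0.951). Lipn, Ucn and Npy are near the counting floor in naive animals.

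For 6 gene lists the injury effect differed between genotypes by camera with the preset correlation. The adjusted p was 2.51e-10 for ribosomal protein genes and 3.31e-09 for oxidative phosphorylation genes, both lower in knockout. It was 0.00286 for immediate early genes, 0.0183 for nerve injury genes, 0.0273 for muscle markers and 0.0375 for Schwann cell markers, all higher. With an estimated correlation each of the 6 had 0.956. The ribosomal and oxidative phosphorylation scores of control SNI replicate 23 were 1.14 and 0.975 log2 units above the control naive mean, whereas the other control SNI libraries lay between -0.20 and 0.25. By the preset correlation alone that library is not the whole of the difference, since without it the adjusted p was 5.34e-07 for the ribosomal and 6.43e-06 for the oxidative phosphorylation genes, and the immediate early genes were called too. The oxidative phosphorylation scores of the knockout SNI libraries, -0.335 to -0.222, lay near the -0.201 and -0.175 of the other control SNI libraries. Their ribosomal scores, -0.0677 to 0.0347, lay between the -0.141 and 0.253 of the same control libraries. In naive animals the ribosomal scores did not overlap, at 0.169 to 0.356 in knockout and -0.153 to 0.163 in control. Without replicate 23 the ribosomal scores thus parted the genotypes in naive and not in injured animals. The nerve injury list was not called without control SNI replicate 15 (0.256), nor without control naive replicate 2 or 7, knockout naive replicate 4 or knockout SNI replicate 19. The muscle markers and the Schwann cell markers each lost their call on several omissions, and went as far as 0.906 without control SNI replicate 15 and 0.491 without knockout SNI replicate 21.

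Genes that rose in naive knockout animals carried 8mers of the cluster in 47.6% of cases. Long or unusual 3′ UTRs are argued against as the cause by 1000 matched triples of other 8mers, which reached at most 19.6% of the same genes. Loss of repression by the cluster would also need the sites in libraries that share no animal with the naive ones, and among genes higher in injured knockout animals the odds ratio was 9.48 (6.33 to 14.2), with 1 of 60 lower genes carrying a site. These values are consistent with relief from the microRNAs at many of the genes that rose, Slc25a1 and Cacna2d2 among them, as a hypothesis that no test of a single site has addressed. Genes without a site, such as Mrgpra3 and Mrgprb4, may change through other genes, or by a change in neuron classes that bulk tissue cannot show.

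The naive knockout differences were set against other explanations. Of 100 of the 126 splits of the 9 libraries only the real one, 1 split, called as many genes (321, against at most 18 in the others). That argues against chance, at a share of 1 in 100. The other splits mix the groups, so real differences count as spread in them and lower their counts. Passenger DNA around the floxed cluster would concentrate calls on chromosome 6, but genes within 20 Mb had an odds ratio of 1.1 (0.295 to 2.89), just under the 3-fold set as the bound. Wild-type animals among the controls, and with them the Cre allele alone, were examined by a fit in which every animal carries Cre. It called 709 genes, 312 of the 321 among them. Dropping the wild types also removes control SNI replicates 18 and 23, which changes the shared spread. The count for injury in knockout, which has no wild-type library, rose in that fit too. The rise to 709 therefore decides nothing about wild-type animals. The 312 retained calls show only that these genes still differ when every animal carries Cre, under that changed spread. Strain differences elsewhere in the genome stay open, as untested.

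More genes passed for injury in knockout (1717) than in control animals (421). The splits argue against chance for each count, at shares of 1 of 56 in control and 1 of 35 in knockout, the real ones (at most 2 genes in any other). A larger scatter among the control SNI libraries was weighed: their median SD was 2.01 times that of knockout SNI, and 1.07 times without replicate 23. Fits of the compared groups alone called 213 and 4438 genes. The 421 and 1717, however, come from 1 fit with 1 shared spread per gene, so this scatter enters both tests. The separate fits, where it enters the control comparison alone, do not measure its part in the gap between 421 and 1717. Without replicate 23 injury in control still called fewer genes than the 1717, and a gap also remained with quality weights. Both settings leave less weight on the control SNI group, so they do not decide how much of the gap is scatter. A larger injury response in knockout cannot be told apart, since the interaction of the nerve injury genes was 0.254 log2 units (-0.114 to 0.621) with 0 genes called, and injured knockout and control animals come from separate ranges of animal numbers.

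For the interaction 100 of 100 drawn splits called at least as many genes as the real 0, as any split must, so that count decides nothing. The split that exchanges control SNI replicates 15 and 23 with knockout SNI replicates 19 and 21 called 101, and points to a structure of the samples whose nature was not tested. The 10 splits for knockout against control after injury are too few to judge chance (1 as large, 177 genes against at most 2).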

How the results depend on the processing

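Limma-voom with sample quality weights and the DESeq2 fit with control SNI replicate 23 left out were chosen after the data had been seen. The other alternatives had been fixed in advance. Counts below are of genes at an adjusted p under 0.05 beside 321, 421, 1717, 177 and 0 for knockout against control in naive animals, injury in control, injury in knockout, knockout against control after injury, and the injury effect compared between genotypes. No paired analysis was possible because the replicate numbers are unique across the groups and 1 library came from each animal. For every change of a count or call given here the cause was not tested, except where fewer libraries are named as the setting itself.

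Each count stayed within 1.5 times its value with DESeq2 size factors, with a minimum of 1 CPM in 3 libraries, with limma-voom, and with the Xist and Y-linked level as a covariate. Without a filter the injury effect compared between genotypes gave 1 gene in place of 0, and the other counts stayed within that range. The DESeq2 Wald test gave 515 genes in naive animals (316 of the 321 among them), 673 for injury in control (416 shared), 925 for knockout against control after injury (163 shared, 436 higher and 489 lower) and 12 for the compared injury effect. With control SNI replicate 23 left out, DESeq2 gave 982 for injury in control, 281 for knockout against control after injury and 8 for the compared effect. Quality weights, which gave that library a weight of 0.143, led to 1027, 881, 4995, 361 and 3 genes, and 1 surrogate variable to 539 in naive animals and 2787 for injury in knockout. With only the compared groups in the fit the counts were 1017 (317 shared), 213 (208 shared), 4438 (1676 shared) and 0, so that for knockout against control after injury none of the 177 genes passed when the spread was estimated from 6 libraries. For the compared injury effect that setting equals the fit of 4 groups and was not run separately. Cre carrier status as a term gave 273 genes for injury in control and 47 for knockout against control after injury, where 1 of 3 control libraries is a Cre carrier. Without the wt libraries the counts were 709 (312 shared), 259 (157 shared), 4745 (1717 shared), 74 (44 shared) and 1, and the lone control SNI library left was assumed to vary like the other groups. The range of animal numbers as a term could be fitted only for naive animals and gave 270 genes, 266 of them shared.

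Leaving out 1 library gave 151 (without knockout naive 9) to 229 (without control naive 3) genes in naive animals, and every omission but that of control naive 3 took the count down by more than 1.5 times. Omissions gave 283 (without control SNI 18) to 1506 (without control SNI 15) for injury in control, with 796 without control SNI 23, of which 356 were among the 421. For injury in knockout they gave 587 (without knockout SNI 19) to 1626 (without knockout SNI 13), with 1127, 1122, 870 and 802 without knockout naive 4, 5, 8 and knockout SNI 21. For knockout against control after injury they gave 57 (without knockout SNI 19) to 3558 (without control SNI 15), with 435 without control SNI 18, 63 without knockout SNI 21, 127 without control SNI 23 and 153 without knockout SNI 13. For the compared injury effect they gave 0 to 1235 (without control SNI 15), and 1 gene each without control SNI 18, control SNI 23 or knockout naive 4. Control SNI replicate 15 carries the Wnt1-Cre allele and the other control SNI libraries do not, and without it the group holds the deviating replicate 23 and 1 other library.

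The seed-site shift in naive animals kept its sign in every setting and in every omission, and it lost its unadjusted call only with 7mer-m8 sites added (0.0205, exact p = 0.167). After injury the shift above the median of matched triples of other 8mers was 0.105 and passed on the smallest p the triples can give, while the exact permutation test on 6 libraries cannot. The p from the triples ranks other 8mers on fixed group means and holds no spread between animals, so it does not replace the permutation test. The shift for injury in control went from -0.00766 (without control SNI 18) to 0.0728 (without control SNI 23), where it passed without adjustment, at the smallest p those libraries can give. The covariance of naive knockout changes and control injury changes above that of the simulation was 0.00240, and went from -0.00157 (without control naive 7) to 0.0105 (without control SNI 15). With the control naive libraries split so that the comparisons share none, the covariance itself was 0.00819.

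The preset correlation of 0.01 decided most list calls. With an estimated correlation the called lists numbered 0, 1, 1, 1 and 0 in place of 10, 11, 10, 9 and 6. The nerve injury genes held for injury in control and for injury in knockout, and the microRNA targets held for knockout against control after injury. In naive animals the adjusted p became 0.0579 for the microRNA targets, 0.141 for the pruriceptor markers, 0.581 for cholesterol synthesis, 0.787 for the opioid and GABA receptors, and 0.975 for the non-peptidergic, C low-threshold, macrophage and muscle markers, the mechanosensitive channels and the ribosomal genes. For injury in control it became 0.193 for the macrophage markers, 0.533 for the complement and cytokine genes and 0.735 for the A-fibre, adipocyte and Schwann cell markers, the sodium channels, the mechanosensitive channels, and the ribosomal, immediate early and histocompatibility genes. For injury in knockout it became 0.204 for the microRNA targets, 0.611 for the complement and cytokine genes, the immediate early genes and the macrophage markers, and 0.992 for the adipocyte and muscle markers and the ribosomal, matrix and oxidative phosphorylation genes. For knockout against control after injury it became 0.506 for the pruriceptor markers and 0.659 for cholesterol synthesis, the calcium channels, the muscle markers, and the ribosomal, immediate early, nerve injury and oxidative phosphorylation genes. For the compared injury effect all 6 lists went to 0.956: the ribosomal, oxidative phosphorylation, immediate early and nerve injury genes and the muscle and Schwann cell markers. Camera without weights called 7 lists for injury in control, where the A-fibre and adipocyte markers, the immediate early genes and the sodium channels went to 0.0538, and it took the Schwann cell markers of the compared effect to 0.0657. DESeq2 size factors added the microRNA targets (0.0498) and the red blood cell genes (0.0440) for injury in control. Omissions left 5 (without control naive 6) to 16 (without control naive 3) called lists for injury in control and 8 (without control SNI 23) to 15 (without control SNI 18) for knockout against control after injury.

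In naive animals, adjusted p of the calls that 1 omission ended went from 0.00146 (without control naive 3) to 0.0539 (without control naive 6) for the mechanosensitive and TRP channels, 0.00846 (without control naive 7) to 0.0676 (without knockout naive 9) for the opioid and GABA receptors, crossing too without control naive 2, 0.000527 (without control naive 3) to 0.0576 (without knockout naive 8) for the non-peptidergic markers, 0.0108 (without knockout naive 9) to 0.134 (without knockout naive 4) for the C low-threshold markers, crossing too without control naive 2, 6 and knockout naive 8, 0.00408 (without knockout naive 9) to 0.259 (without knockout naive 4) for the macrophage markers, crossing too without control naive 2, and 1.75e-05 (without knockout naive 5) to 0.267 (without knockout naive 8) for the muscle markers, crossing too without control naive 6. In naive animals, lists that 1 omission brought past the threshold went from 0.0405 (without control naive 7) to 0.515 (without knockout naive 8) for the potassium channels, 0.00287 (without knockout naive 5) to 0.864 (without knockout naive 8) for the histocompatibility genes, crossing too without control naive 3, 7, 0.0132 (without control naive 7) to 0.87 (without control naive 1) for the interferon response genes, and 0.0388 (without control naive 2) to 0.861 (without control naive 1) for the matrix genes.

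For injury in control, adjusted p of the calls that 1 omission ended went from 0.00188 (without control SNI 15) to 0.443 (without control SNI 23) for the sodium channels, crossing too without control naive 1, 2, 6 and control SNI 18, 0.000539 (without control SNI 15) to 0.887 (without control SNI 23) for the mechanosensitive and TRP channels, crossing too without control naive 2, 6 and control SNI 18, 0.00146 (without control SNI 15) to 0.367 (without control SNI 18) for the A-fibre markers, crossing too without control naive 1, 2, 6 and control SNI 23, 0.00191 (without control naive 3) to 0.0992 (without control SNI 15) for the histocompatibility genes, crossing too without control naive 2, 6, 0.00185 (without control SNI 15) to 0.316 (without control SNI 18) for the adipocyte markers, crossing too without control naive 1, 2, 6, 0.0011 (without control naive 3) to 0.138 (without control naive 7) for the immediate early genes, crossing too without control SNI 15, 18 and control naive 2, 6, and 8.81e-12 (without control SNI 15) to 0.859 (without control SNI 23) for the ribosomal protein genes. For injury in control, lists that 1 omission brought past the threshold went from 0.0206 (without control SNI 23) to 0.333 (without control SNI 18) for the microRNA targets, crossing too without control naive 1, 7, 0.0451 (without control SNI 15) to 0.965 (without control naive 6) for the calcium channels, 0.000539 (without control SNI 15) to 0.878 (without control SNI 23) for the potassium channels, crossing too without control naive 3, 7, 0.000732 (without control SNI 15) to 0.878 (without control SNI 23) for the glutamate receptor and release genes, crossing too without control naive 3, 7, 0.0337 (without control naive 3) to 0.809 (without control SNI 18) for the non-peptidergic markers, 0.0108 (without control SNI 18) to 0.239 (without control SNI 15) for the pruriceptor markers, crossing too without control naive 7, 0.0272 (without control SNI 15) to 0.764 (without control naive 6) for the C low-threshold markers, 0.00626 (without control SNI 15) to 0.87 (without control SNI 18) for the matrix genes, crossing too without control naive 1, 3 and control SNI 23, 0.00209 (without control SNI 23) to 0.853 (without control SNI 18) for the endothelial markers, crossing too without control naive 3, 0.00304 (without control naive 1) to 0.452 (without control SNI 15) for the red blood cell genes, crossing too without control naive 2, 7 and control SNI 23, 0.0111 (without control SNI 15) to 0.992 (without control naive 6) for the muscle markers, and 2.25e-08 (without control SNI 23) to 0.276 (without control naive 6) for the oxidative phosphorylation genes, crossing too without control SNI 15, 18. Without control SNI 23 the oxidative phosphorylation genes reversed their direction, to lower after injury, and for the ribosomal genes the remaining control SNI libraries went opposite ways, with scores of -0.141 and 0.253.

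For injury in knockout, adjusted p of the calls that 1 omission ended went from 8.73e-05 (without knockout SNI 21) to 0.224 (without knockout SNI 19) for the adipocyte markers. In that comparison, lists that 1 omission brought past the threshold went from 0.0218 (without knockout SNI 21) to 0.822 (without knockout naive 8) for the Schwann cell markers, 0.000722 (without knockout SNI 13) to 0.831 (without knockout SNI 19) for the histocompatibility genes, crossing too without knockout naive 8, 0.000189 (without knockout SNI 19) to 0.996 (without knockout SNI 21) for the interferon response genes, crossing too without knockout naive 4, 9, and 0.0251 (without knockout SNI 13) to 0.522 (without knockout SNI 21) for the endothelial markers.

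For knockout against control after injury, adjusted p of the calls that 1 omission ended went from 7.59e-06 (without knockout SNI 13) to 0.0997 (without knockout SNI 19) for the nerve injury genes, crossing too without control SNI 15, 0.00159 (without knockout SNI 21) to 0.121 (without control SNI 23) for the calcium channels, 6.77e-07 (without control SNI 23) to 0.125 (without control SNI 18) for the cholesterol synthesis genes, crossing too without knockout SNI 13 and control SNI 15, 1.56e-09 (without control SNI 15) to 0.283 (without control SNI 23) for the ribosomal protein genes, and 5.03e-11 (without control SNI 18) to 0.0627 (without control SNI 23) for the oxidative phosphorylation genes. For knockout against control after injury, lists that 1 omission brought past the threshold went from 0.0171 (without control SNI 15) to 0.533 (without knockout SNI 13) for the sodium channels, crossing too without knockout SNI 19, 21, 0.0276 (without control SNI 23) to 0.789 (without knockout SNI 21) for the mechanosensitive and TRP channels, 0.0217 (without knockout SNI 13) to 0.647 (without control SNI 15) for the opioid and GABA receptors, crossing too without control SNI 18, 0.00607 (without control SNI 15) to 0.283 (without control SNI 23) for the glutamate receptor and release genes, crossing too without knockout SNI 19, 21, 0.0447 (without knockout SNI 19) to 0.366 (without knockout SNI 21) for the peptidergic markers, 0.00108 (without control SNI 18) to 0.88 (without control SNI 15) for the C low-threshold markers, crossing too without knockout SNI 13 and control SNI 23, 7.59e-06 (without knockout SNI 13) to 0.885 (without knockout SNI 21) for the Schwann cell markers, crossing too without control SNI 18, 0.0397 (without control SNI 18) to 0.988 (without control SNI 15) for the lymphocyte markers, 0.00365 (without knockout SNI 13) to 0.653 (without control SNI 18) for the histocompatibility genes, 0.00565 (without knockout SNI 19) to 0.996 (without control SNI 15) for the interferon response genes, 0.0038 (without knockout SNI 13) to 0.988 (without control SNI 15) for the matrix genes, crossing too without control SNI 18, 0.044 (without control SNI 18) to 0.992 (without knockout SNI 21) for the endothelial markers, 0.0312 (without knockout SNI 19) to 0.988 (without control SNI 15) for the red blood cell genes, and 0.0142 (without knockout SNI 21) to 0.988 (without control SNI 15) for the adipocyte markers, crossing too without knockout SNI 13 and control SNI 18.

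For the compared injury effect, adjusted p of the calls that 1 omission ended went from 0.000102 (without knockout SNI 13) to 0.256 (without control SNI 15) for the nerve injury genes, crossing too without control naive 2, 7 and knockout naive 4 and knockout SNI 19, 1.29e-07 (without knockout SNI 13) to 0.491 (without knockout SNI 21) for the Schwann cell markers, crossing too without control SNI 15, 23 and knockout naive 4, 5, 9 and control naive 1, 3 and knockout SNI 19, and 7.99e-08 (without knockout SNI 19) to 0.906 (without control SNI 15) for the muscle markers, crossing too without control naive 1, 7 and knockout naive 5, 9 and control SNI 23 and knockout SNI 13, 21. For the compared injury effect, lists that 1 omission brought past the threshold went from 0.00745 (without control SNI 15) to 0.537 (without control SNI 23) for the calcium channels, crossing too without knockout SNI 21 and control naive 3, 0.0126 (without control SNI 15) to 0.851 (without control SNI 23) for the potassium channels, 0.0288 (without control SNI 15) to 0.847 (without control SNI 23) for the mechanosensitive and TRP channels, 0.00552 (without control SNI 15) to 0.34 (without control SNI 23) for the glutamate receptor and release genes, crossing too without knockout SNI 19, 21 and control naive 7, 0.00284 (without control SNI 15) to 0.752 (without control SNI 23) for the macrophage markers, 0.00722 (without knockout SNI 19) to 0.953 (without control naive 2) for the histocompatibility genes, 0.00159 (without knockout SNI 19) to 0.907 (without knockout naive 8) for the interferon response genes, and 0.000863 (without knockout SNI 13) to 0.906 (without control SNI 15) for the matrix genes, crossing too without control SNI 18 and control naive 2.

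Among the called genes that the naming rule gives, 23 of 33 kept their call in every setting in naive animals, 20 of 52 for injury in control, 38 of 83 for injury in knockout, and 0 of 35 for knockout against control after injury, where the fit with only the compared groups calls no gene. None of them changed direction in any setting. With the uncalled genes that were followed too, the genes numbered 66, 82, 101 and 63. Over these, calls were lost in 47, 176, 194 and 169 combinations of gene and setting and gained in 71, 32, 51 and 58. The side of the threshold stayed in 1266, 1430, 1573 and 892, which include uncalled genes that stayed uncalled. These counts therefore give no share of calls lost. A count of 0 can miss real changes: in simulated counts with changes of 1.5-, 2- and 4-fold, the test recovered 49.3%, 71.6% and 92.4% in naive animals, and 11.9%, 46.3% and 83.3% for the compared injury effect. Every simulated library had the same spread for a gene, so the larger scatter of the control SNI libraries is left out. Control SNI 23 has 5.25 M counts, against 7.59 M or more in every other library.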

Other observations

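The seed-site tests for injury in knockout, the shares of called genes with a site, and the choice to name Adgrd1, Anks1b, Cd109, Ildr2, Mettl7a3 and Tmc5 were chosen only after the result was seen. These 6 genes were lower in naive knockout animals and higher after injury in control animals. The comparisons share the control naive libraries, so the value for independent lists is not a chance value for this number. Lists without a call in any of the 5 comparisons were those of peptidergic nociceptors (smallest adjusted p 0.11, lower in knockout after injury), satellite glia (0.346), lymphocytes (0.277), neutrophils and mast cells (0.667), endothelium and pericytes (0.0597), red blood cells (0.0555), spinal cord glia and interneurons (0.295, with 5 of 18 members expressed), type I interferon response (0.175), heat shock (0.293), glutamate receptors and release (0.0597), potassium and HCN channels (0.126), and sex-linked genes (0.667).

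By the level of Xist, control naive replicate 6, knockout naive replicates 8 and 9, control SNI replicates 15 and 23 and knockout SNI replicate 19 were female and the other 9 libraries male. No sex is given in the labels, and with the Xist and Y-linked level as a covariate 299, 324, 1581, 122 and 0 genes passed in the 5 comparisons. Animal numbers run from 1041 to 1082 in naive animals, from 948 to 956 in injured knockout and from 974 to 976 in injured control animals, so injury and the order of the animals, and genotype and that order after injury, are the same split.

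In injured knockout against naive knockout animals 155 of 1126 genes that rose carried an 8mer of the cluster (13.8%, odds ratio 1.61, Fisher's exact p = 6.51e-07), in a comparison where both groups carry the knockout genotype. Control animals had 11.9% among the genes that rose (Fisher's exact p = 0.106). Both tests count genes as independent. In the knockout comparison the shift over all genes was 0.10 (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0714), which misses 0.05. No triples of other 8mers were set against this comparison, so the length or composition of the 3′ UTRs stays open for it.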
